A study of Mus musculus with 4 samples.

How the data were processed

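The data are 4 single-colour arrays of mouse dorsal raphe nucleus RNA, 1 array per group, each from RNA pooled from 5 mice, per the labels. The groups are non-stressed WT, stressed WT, stressed D2R-KO and stressed D2LR-KO, and there is no non-stressed knockout array. Per the labels, total RNA was extracted with the Qiagen RNeasy mini kit, amplified as amino allyl aRNA with the Ambion MessageAmp II kit, labelled with Cy5 and hybridised by the protocol of the array maker, Toray. Per the file headers, each array was scanned 3 times at different gain, and how the scans were combined is not given in the sources used here. Each scanner file holds, per the file headers, the median intensity of every spot at 635 nm and the median intensity around it, neither of them background-subtracted. The authors' deposited value table also holds intensity on a linear scale. From the values, each deposited intensity equals the spot median minus 1 constant per array (36.7 to 38.8), divided by 1 factor per array (1.51 to 2.05), so that the array median is 25, and 1499 to 1540 probes per array have no value. The submitters' own steps for that table are not given in the sources used here.

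Signal was computed from the spot medians. The blank spots of each array served as negative controls for the normexp background correction of limma 3.58.1 (function nec) in R 4.3.3, with an offset of 50, followed by log2 and quantile normalization over all 4 arrays. Folds are therefore on the log2(signal + 50) scale. The blank spots were preferred to the brightness around each spot after looking at the files, because that brightness followed the spot itself (r = 0.884 to 0.962), and the other choice is among the alternatives. A probe was detected on an array when its spot was above the mean plus 2 SD of the blank spots, a limit of 38.0 to 40.2 against a median spot of 67.1 to 80.1, and 91.0% to 91.6% of gene probes passed it. The highest spot per array lay between 45514 and 57662, and the level at which the combined scans saturate is not known here. Probes were given genes by the series' own probe table, in which 16631 of 23473 probes have 1 gene symbol and 6842 have none here. Of 16446 symbols, 12501 stood in the RefSeq gene table, 3883 older ones were updated and 62 were kept as given. For 229 genes with more than 1 probe, the probe with the highest mean signal was kept, and 9 probes with a spot marked as not usable were left out, which gave 16383 genes. Further steps were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

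The 6 comparisons are each stressed group against non-stressed WT, each knockout against stressed WT, and D2LR-KO against D2R-KO. With 1 array per group no test was possible, and a gene was counted as higher or lower when it differed at least 2-fold and was detected on at least 1 of the 2 arrays. Where it was detected on only 1, the fold is a bound and is written as at least that size. For each comparison against non-stressed WT the 10 genes with the largest differences in each direction are named, and 6 for the other comparisons, among genes detected on both arrays whose brighter signal was at or above the median of detected genes. Predicted genes were counted and not named, namely 19 for stressed WT against non-stressed WT, 26 for D2R-KO against stressed WT, 21 for D2LR-KO against stressed WT and 0 otherwise. Drd2, Htr1a, Tph2 and Slc6a4 are given on every array, as was planned for Fev, which no probe names here.

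For 30 gene lists the number of members at least 1.5-fold higher and lower was counted, and the list median of log2 folds was placed among 10000 random lists of equal size matched on mean signal in 20 bins. Its percentile is a description of these arrays, and the number of other settings in which a list stayed in the lowest or highest 2.5% is given where more than 1 setting lost it. The comparisons, thresholds, gene lists, rules for naming genes and most alternatives were fixed before the data were examined. A further 8 lists of brain region markers were written after a few gene values had been seen and before any region value was computed. Overlaps between comparisons that share the control array were set beside the product expected for independent lists. They were also set beside 100 simulations of arrays without group effects, which assume an equal spread of all arrays. The simulated spread was drawn, by signal level, from the differences between the real arrays, so any real group effect enters it. Fold changes of comparisons with no array in common were correlated across genes. No value has a replicate error. Repeated control spots on the arrays gave SDs of a log2 difference between 2 arrays of 0.149 to 0.237, which cover spots on an array and not mice or labellings.

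The procedure was tested on simulated data for stressed WT against non-stressed WT with 16383 genes. Of 15283 unchanged genes 0 were called. All simulated arrays were built from the non-stressed WT array, with a scale factor per array and the spread of spots within an array. Differences between mice, dissections or labellings were not simulated, so this 0 gives no rate of false calls for the real arrays. Simulated 2-fold differences were called in 0% of 50 genes, 3-fold in 38% and 4-fold in 48%, with median measured folds of 1.41, 1.69 and 1.88. Among the brighter of them, 82.6% of 3-fold and 95.7% of 4-fold differences were called. A list with every member shifted 1.5-fold reached percentile 100, and an unshifted list lay at 48.6.

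Alternatives tried were scaling each array to a single median, cyclic loess, an offset of 16, plain subtraction of the blank level with values under the detection limit set to it, the value table as deposited, the mean of all probes of a gene, other filters on dim genes, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. The background around each spot and quantile normalization without the stressed WT array were added after seeing the data. Probes without a gene name were counted and are not named. The scanner images were not analysed here.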

Results

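RNA labelled as mouse dorsal raphe nucleus, the brainstem nucleus that holds most of the serotonergic neurons projecting to the forebrain, was measured on 4 single-colour DNA microarrays. Each array carried RNA pooled from 5 male C57BL/6J mice aged 10 weeks. The groups were non-stressed wild-type mice (WT), stressed WT mice, stressed mice without the dopamine D2 receptor (D2R-KO) and stressed mice without the long form of that receptor (D2LR-KO). Stress was a forced swim of 6 min on each of 4 days, and tissue was taken 12 h after the last swim. The series asks which genes differ after forced swimming in each genotype, in connection with serotonergic neurons and the serotonin 1A receptor. There was 1 array per group, so no value below has a replicate error, no difference could be tested, and the number of arrays limits the precision. Between 21363 and 21496 of 23465 gene probe spots per array were above the detection limit set by the blank spots. Fold values are on the log2(signal + 50) scale, which understates the differences of dim genes, so the authors' deposited intensities (array median 25) are given beside many of them.

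The targeted gene was read first. Drd2, which encodes the D2 receptor (probe M200013811), had deposited intensities of 26.8 in non-stressed WT, 43.8 in stressed WT, 20.9 in stressed D2R-KO and 48.3 in stressed D2LR-KO. Its log2 fold was -0.16 for D2R-KO and 0.48 for D2LR-KO against non-stressed WT, and -0.60 and 0.04 against stressed WT. D2LR-KO exceeded D2R-KO by 0.64, which turned to -0.09 with the background taken around each spot. The position of this probe relative to the deleted parts of the gene is not known here, so its level checks the labels little. Htr1a, the serotonin 1A receptor, had intensities of 28.7, 22.6, 33.7 and 21.7 in the same order of arrays, and none of its 6 log2 folds exceeded 0.29 in size. Tph2, the enzyme that limits serotonin synthesis in neurons, had intensities of 31.4 in non-stressed WT, 10.7 in stressed WT, 264.6 in D2R-KO and 151.5 in D2LR-KO. Slc6a4, the serotonin transporter, had intensities of 11.6, 6.8, 89.6 and 43.5. Slc6a4 thus lay below the array median on both WT arrays, and Tph2 did so in stressed WT. How much dorsal raphe tissue each pool held is not known here, which limits every comparison of a knockout with a WT array. Fev, the other gene set to be named on every array, was not named by the annotation used here and is not reported.

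**Figure D1:**
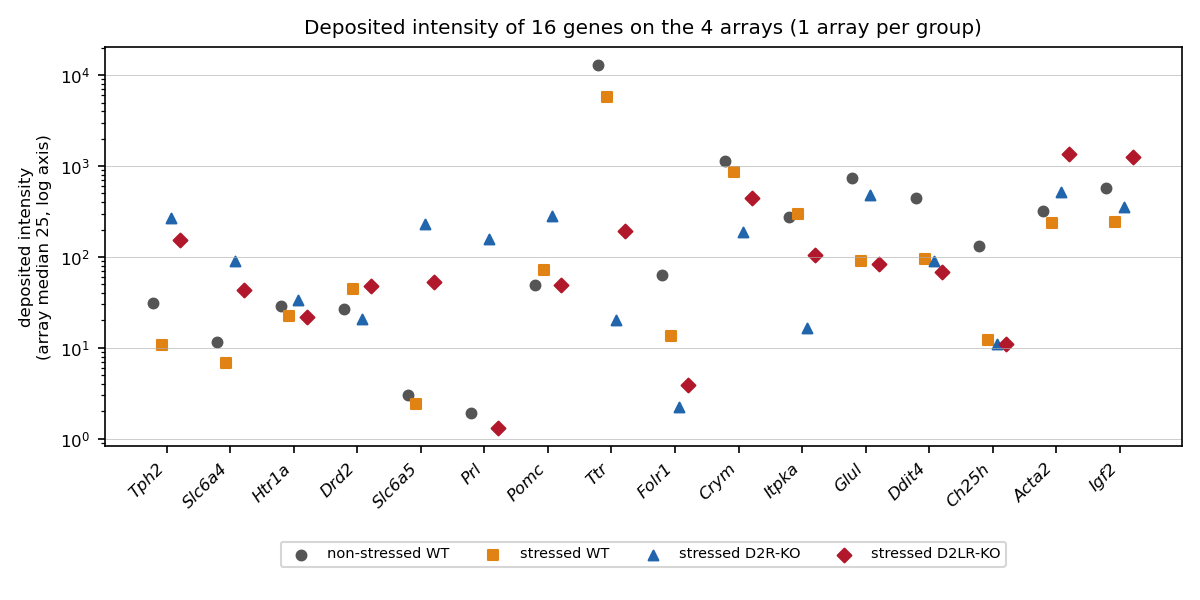
Deposited intensity of 16 genes (log axis, array median 25) on the 4 arrays; each point is 1 array, so there are no error bars. Tph2 and Slc6a4 lie higher on both knockout arrays than on both WT arrays, and Ttr is at 12884 in non-stressed WT and 20.3 in D2R-KO; Prl has no deposited value on the stressed WT array.

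Stressed WT was set against non-stressed WT to ask what differs with forced swimming in 1 genotype. The largest differences were on the lower side. Glul, glutamine synthetase of astrocytes, was 5.75-fold lower, with deposited intensities of 728.9 in non-stressed and 90.6 in stressed WT. Slc17a6, the vesicular glutamate transporter of subcortical neurons, was 4.40-fold lower, Sucla2, a succinyl-CoA synthetase subunit, 4.17-fold lower, and Cox5a, a cytochrome c oxidase subunit, 3.92-fold lower. Paip2, which regulates poly(A)-binding protein, was 4.78-fold lower, Ch25h, cholesterol 25-hydroxylase, 3.86-fold, Vps50 3.76-fold, the phosphatase subunit Ppp2r5e 3.64-fold, the co-chaperone Dnajc7 3.64-fold and Reep5 3.56-fold. The higher genes were led by Rfpl4 (4.36-fold), the lymphocyte receptor Btla (4.11-fold), Galp, which encodes galanin-like peptide (4.05-fold, 71.1 against 305.6), the nuclease subunit Slx1b (3.66-fold), Ndufa4l2 (3.44-fold) and Dbp, a transcription factor driven by the circadian clock (3.15-fold). Crip3 was 3.10-fold, Fbxo16 3.05-fold, Zfp697 3.04-fold and the microtubule kinase Mark4 3.03-fold higher. The chemokine gene Cxcl1 was not detected on the stressed WT array and was at least 5.99-fold lower there. In all, 229 genes were at least 2-fold higher and 335 at least 2-fold lower among 15643 compared, and the arrays correlated at r = 0.963 across genes.

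Of the 30 gene lists, 7 had a median log2 fold among the lowest 2.5% of matched random lists in stressed WT, and none had one among the highest 2.5%. The heat shock and unfolded protein response list had 9 of 17 members at least 1.5-fold lower and none higher (median -0.68, percentile 0.01), with the endoplasmic reticulum chaperone Hspa5 at -1.41, Dnajb9 at -1.06, Atf4 at -1.06 and Dnajb1 at -0.98. Among immediate early genes, which neurons switch on with activity, 7 of 24 were lower and 1 higher (median -0.21, percentile 0.40), with Fos at -1.56, Dusp6 at -1.41 and Ier2 at -1.15. The GABA list had 3 of 13 lower (median -0.40, percentile 1.10), led by the receptor subunit Gabra3 at -1.19, and the interferon response list had 4 of 18 lower and 3 higher (median -0.25, percentile 0.16), with Ifit3 at -0.81 and Rsad2 at 0.74. The choroid plexus and ependyma list had 6 of 12 lower (median -0.62, percentile 0), with Folr1 at -1.13 and Kl at -1.05. The meninges and fibroblast list had 4 of 11 lower (median -0.47, percentile 0.445), with Slc6a13 at -1.07 and Igf2 at -0.86. The endothelial and pericyte list had 5 of 16 lower (median -0.39, percentile 0.21), with Ly6c1 at -0.99 and Flt1 at -0.95; that median turned to 0.05 with the background around each spot. The GABA list stayed among the lowest 2.5% in 5 of 8 other settings and the meninges and endothelial lists in 6 of 8.

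Further lists held members with larger differences while the list median stayed within the random range. In oxidative phosphorylation 10 of 36 members were lower and 4 higher (median -0.19, percentile 4.40), with Atp5c1 at -1.78 and Cycs at -1.34. Among glucocorticoid-induced genes 5 of 18 were lower and 2 higher (median -0.15, percentile 6.98), with Ddit4 at -1.76, Tsc22d3 at -1.56 and Sgk1 at -1.25. The astrocyte list had 4 of 14 lower, including the connexins Gjb6 at -1.48 and Gja1 at -1.08 (median -0.20, percentile 11.6), and the microglia list had 1 of 15 lower (median -0.23, percentile 10.1). The oligodendrocyte and myelin list had 3 of 15 higher and 3 lower (median 0.11, percentile 80.9), with Mag at 1.15 and Ugt8a at -1.13. Housekeeping genes had 4 of 12 lower and 2 higher (median -0.22, percentile 12.5), with Tfrc at -1.11, Actb at 0.94 and Ywhaz at 0.86, against 0 and 1 past 1.5-fold in D2R-KO and D2LR-KO. The circadian clock list had a median of -0.05 (percentile 26.8), with Dbp at 1.65 and Arntl at -0.91. The median was 0.06 for Gi signalling, RGS, GRK, arrestin and GIRK genes (percentile 83.7), 0.13 for the dopamine neuron and dopamine receptors list (percentile 92.5), -0.02 for serotonin receptors (percentile 22.7), 0.06 for cerebellum markers (percentile 68.6), 0.12 for cholinergic and motor nuclei (percentile 95.6) and -0.03 for the oligodendrocyte precursor list (percentile 43.0). The serotonergic neuron list had 1 of 14 lower, Tph2 at -0.63, which turned to 0.08 with the background around each spot, and a median of -0.04 (percentile 31.5).

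These counts compare 1 array with 1 array. With each array scaled to a single median in place of quantile normalization, 30 genes were higher and 893 lower. With the background around each spot the split turned round, to 749 higher and 576 lower, and Paip2, Slc17a6 and Dnajc7 turned from lower to higher (1.72, 0.95 and 0.75).

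**Figure D2:**
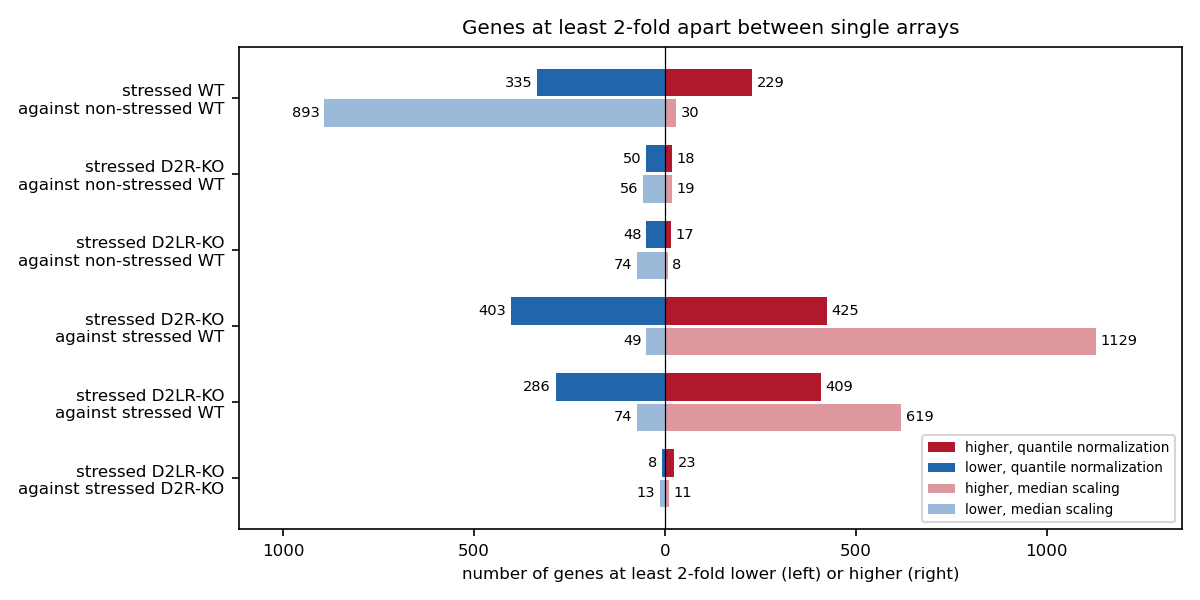
Number of genes at least 2-fold lower (left) or higher (right) in each of the 6 comparisons of single arrays, after quantile normalization (dark bars) and after scaling each array to a single median (pale bars). Comparisons that include the stressed WT array hold 564 to 828 genes after quantile normalization, the others 31 to 68, and the scaling moves the split most where stressed WT is included.

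Stressed D2R-KO against non-stressed WT changes stress and genotype at once. The higher side was led by Slc6a5, by pituitary hormone genes and by genes of serotonergic neurons. Slc6a5, the neuronal glycine transporter, was 7.36-fold higher (deposited intensity 3.0 against 231.9), Tph2 4.38-fold and Slc6a4 2.74-fold higher. Prl (prolactin, 5.54-fold), Pomc (proopiomelanocortin, 3.63-fold) and Gh (growth hormone, 2.49-fold) were higher, together with Mbl2 (2.96-fold), Jaml (2.67-fold), the slow troponin gene Tnnt1 (2.46-fold) and Anp32a (2.33-fold). The pituitary hormone genes stood out on the D2R-KO array only, with deposited Prl of 156.3 there, 1.9 in non-stressed WT and 1.3 in D2LR-KO. Whether these hormone transcripts came from the raphe was not tested. Ttr, transthyretin, the main secreted protein of the choroid plexus, was 273-fold lower. The inositol trisphosphate kinase Itpka was 6.58-fold lower, Crym 5.72-fold, the phosphodiesterase Pde1a 3.82-fold, Icam5 3.35-fold and the transcription factor Dlx1 3.32-fold. Cxcl1 was 5.90-fold, Guca1a 4.35-fold, the stress-regulated mTOR inhibitor Ddit4 4.12-fold and Ch25h 3.87-fold lower. In all, 18 genes were at least 2-fold higher and 50 lower among 15607 compared (r = 0.990 across genes).

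The serotonergic neuron list had 4 of 14 members higher and none lower (median 0.19, percentile 99.99), with the pteridine regulator Gchfr at 1.17 and Gata3 at 0.77 beside Tph2 and Slc6a4. Genes of the pons and medulla, a list written later, were also higher (median 0.40, percentile 100). The oxidative phosphorylation list had a median of 0.14 (percentile 99.7), with 35 of 36 members within 1.5-fold, and the oligodendrocyte and myelin list a median of 0.17 (percentile 99.3), with all 15 members within 1.5-fold and the list among the highest 2.5% in 7 of 9 other settings. Stress neuropeptides and steroid receptors had 5 of 28 lower and 1 higher (median -0.17, percentile 0), with Npy at -1.41, Cck at -1.38 and Pmch at -1.02 against Pomc at 1.86. Immediate early genes had 3 of 23 lower (median -0.25, percentile 0), namely Jun at -0.95, Nr4a1 at -0.87 and Btg2 at -0.72. The GABA list had 3 of 13 lower (median -0.26, percentile 0.01), with Gabrb1 at -0.73. Markers of cerebral cortex and hippocampus, a list written later, were lower on this array too, with 4 of 12 lower and 1 higher (median -0.18, percentile 0.02). Interferon response genes were lower by small amounts (median -0.15, percentile 0, none past 1.5-fold). The choroid plexus and ependyma list had 8 of 12 lower (median -0.81, percentile 0), with Folr1 at -1.54 and Kcne2 at -1.01. The meninges and fibroblast list had 4 of 11 lower (median -0.32, percentile 0.01) and the blood list 1 of 6 lower (median -0.20, percentile 0.37). The astrocyte list had 3 of 14 lower (median -0.12, percentile 1.74), which turned to 0.06 with the background around each spot. Among glutamate genes Gria1 was at -1.22 and Gria2 at -1.02, with a list median of -0.01 (percentile 31.8). From the values as deposited, 353 genes were higher and 422 lower, and with the background around each spot the split turned round, to 532 higher and 256 lower.

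Stressed D2LR-KO against non-stressed WT likewise changes stress and genotype at once. The higher side was led by Acta2 (smooth muscle actin), 3.85-fold, and Tagln (transgelin), 3.06-fold. Crabp2, a retinoic acid binding protein gene, was 2.25-fold and Ogn (osteoglycin) 2.17-fold higher. Tph2 was 2.93-fold, Slc6a5 2.56-fold, Anp32a 2.27-fold, Nupr1 2.23-fold, Rsrp1 2.21-fold and the calcium-binding protein gene Pvalb 2.12-fold higher. Ttr was 61.3-fold lower, and Glul 6.72-fold lower (728.9 against 84.5). Cxcl1 was 5.64-fold, Ddit4 4.76-fold, Guca1a 4.12-fold, Ch25h 3.89-fold, the kinase Sgk1 3.65-fold, the neuronal calcium sensor Hpca 3.45-fold, the glutamate receptor Gria1 3.17-fold and Nptx1 2.97-fold lower. In all, 17 genes were at least 2-fold higher and 48 lower among 15574 compared (r = 0.990 across genes).

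The serotonergic neuron list had 3 of 14 higher and none lower (median 0.25, percentile 100), namely Tph2 at 1.55, Gchfr at 0.88 and Slc6a4 at 0.83. The vesicular transporter Slc18a2, at 0.58, fell just short of 1.5-fold. The pons and medulla list was also higher here (median 0.38, percentile 100), and the cerebral cortex and hippocampus list lower, with 2 of 12 lower past 1.5-fold (median -0.16, percentile 0.05). The meninges and fibroblast list had 4 of 11 higher (median 0.45, percentile 100), with Igf2 at 1.05 and Col3a1 at 0.77, and the endothelial and pericyte list 1 of 16 higher, Acta2 (median 0.16, percentile 99.7). The blood list, of which most measured members are white cell genes, had 1 of 6 higher, the antigen-presenting gene H2-Aa at 0.59 (median 0.30, percentile 99.99). In the oligodendrocyte and myelin list 3 of 15 were higher (median 0.26, percentile 99.97), with Aspa at 0.96, Mag at 0.70 and Opalin at 0.69. Lower lists were choroid plexus and ependyma (8 of 12, median -0.67, percentile 0), GABA (5 of 13, median -0.53, percentile 0, Gabra3 at -1.08 and Slc6a11 at -0.92), immediate early genes (4 of 23, median -0.22, percentile 0, Nr4a1 at -1.20 and Dusp1 at -0.93) and glucocorticoid-induced genes (4 of 18, median -0.18, percentile 0.04). Stress neuropeptides and steroid receptors had 6 of 28 lower (median -0.10, percentile 0.09), with Nts and Cartpt at -1.05, and heat shock and unfolded protein response 1 of 17, Dnajb1 at -0.94 (median -0.22, percentile 0.10). The Akt and GSK3 list had a median of -0.10 (percentile 1.21) with no member past 1.5-fold, Gsk3b being at -0.50, and kept its place among the lowest 2.5% in 6 of 9 other settings. Smaller list medians turned sign with another setting. Pan-neuronal genes at -0.17 (percentile 1.11) and glutamate genes at -0.09 (percentile 0.415) went to 0.01 and 0.03 with the background around each spot, and oxidative phosphorylation at 0.09 (percentile 98.1) went to -0.05 with median scaling. That scaling gave 8 genes at least 2-fold higher and 74 lower, and the values as deposited gave 293 higher and 406 lower. With the background around each spot the split turned round, to 496 higher and 134 lower, and Gria1 and Sgk1 turned to 3.90 and 0.75.

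**Figure D3:**
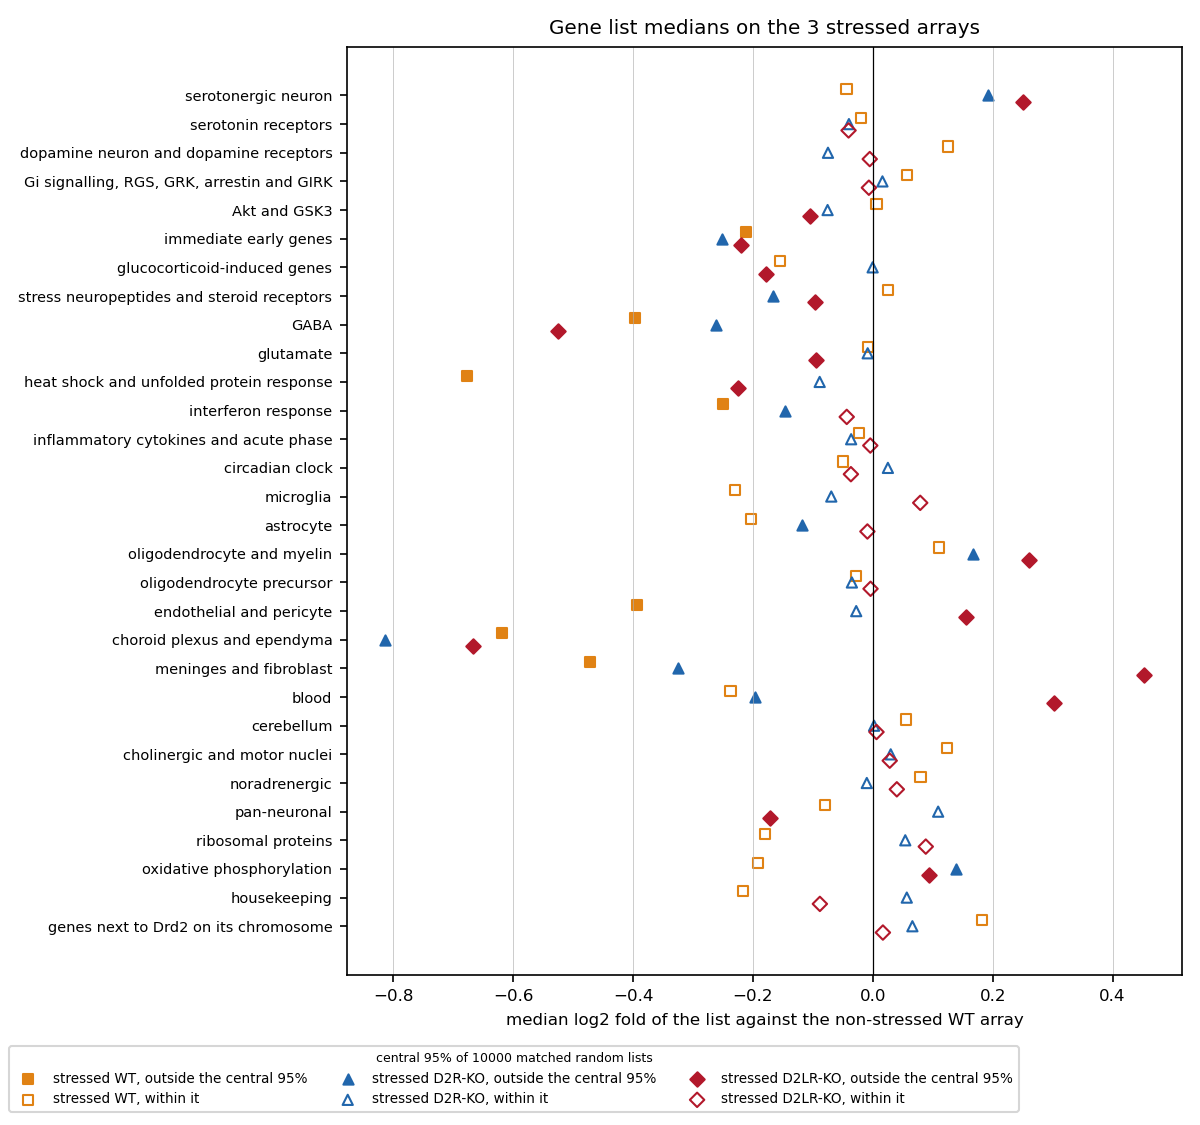
Median log2 fold of each of the 30 gene lists on the 3 stressed arrays against the non-stressed WT array, in the quantile-normalized values. Filled points are in the lowest or highest 2.5% of 10000 random lists matched on signal; serotonergic neuron genes are filled to the right in both knockouts, and choroid plexus, GABA and immediate early genes are filled to the left on all 3 arrays, GABA in stressed WT in 5 of 8 other settings.

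Stressed D2R-KO was set against stressed WT to ask what differs with genotype among stressed mice. Since this comparison and that of stressed WT with non-stressed WT use the same stressed WT array, genes extreme on it take opposite signs in them by construction. Slc6a5 was 7.61-fold and Tph2 6.80-fold higher in D2R-KO, followed by Paip2 (5.30-fold), the hindbrain homeobox gene Hoxb5 (4.84-fold), the secreted phosphoprotein Spp1 (4.72-fold) and Sucla2 (4.50-fold). Prl, not detected in stressed WT, was at least 5.75-fold higher. Ttr was 145-fold lower, Itpka 8.47-fold, Crym 5.57-fold, Galp 4.90-fold, Hpca 4.60-fold and the postsynaptic protein gene Nrgn 4.59-fold lower. The oxidative phosphorylation list had 15 of 36 members higher and 2 lower (median 0.29, percentile 99.0), with Cox5a at 2.13 and Atp5c1 at 1.95. The endothelial and pericyte list had 5 of 16 higher (median 0.37, percentile 98.9), stress neuropeptides and steroid receptors 9 of 28 lower and 2 higher (median -0.19, percentile 0.91, Cartpt at -1.76 and Penk at 1.49), and choroid plexus and ependyma 1 of 12 lower, Ttr (median -0.25, percentile 1.51, kept in 6 of 8 other settings). The serotonergic neuron list had 4 of 14 higher with a median of 0.20 inside the random range (percentile 96.6). The 12 measured genes next to Drd2 on its chromosome had a median of -0.37 (percentile 0.86, 2 lower, Htr3a at -1.09 and Usp28 at -1.06), which became 0.01 with median scaling and kept its place in 4 of 8 other settings. Against non-stressed WT this list stayed within the random range in D2R-KO (median 0.07, percentile 87.0) and in D2LR-KO (median 0.02, percentile 59.8). In stressed WT against non-stressed WT its median was 0.18 (percentile 93.0). In all, 425 genes were at least 2-fold higher and 403 lower among 15655 compared (r = 0.955); median scaling gave 1129 higher and 49 lower.

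For stressed D2LR-KO against stressed WT, the largest differences among the higher genes were those of Crabp2, 7.37-fold, Tagln, 7.05-fold, the matrix protein Mgp, 5.55-fold, and Igfbp7, 4.89-fold, together with Paip2 (5.45-fold) and Cox5a (5.08-fold). Ttr was 32.5-fold lower, Hpca 5.59-fold, Nrgn 4.30-fold, Galp 4.24-fold, the peptide gene Cartpt 4.06-fold and Nptx1 3.65-fold lower. The meninges and fibroblast list had 8 of 11 higher (median 1.01, percentile 100), with Igf2 at 1.91 and Col3a1 at 1.28, the endothelial and pericyte list 10 of 16 higher (median 0.71, percentile 100), with Vtn at 1.51, and the blood list 3 of 6 higher (median 0.58, percentile 99.9). Oxidative phosphorylation had 12 of 36 higher and 2 lower (median 0.27, percentile 98.5), interferon response 2 of 18 higher and 1 lower (median 0.19, percentile 99.0), and ribosomal proteins 5 of 27 higher and 2 lower (median 0.25, percentile 98.2), which turned to -0.04 with the background around each spot and kept its place in 4 of 8 other settings. Stress neuropeptides and steroid receptors had 6 of 28 lower and 1 higher (median -0.26, percentile 0.13), and the noradrenergic list had none of 5 past 1.5-fold (median -0.28, percentile 1.85, Dbh at -0.53), a place kept in only 2 of 8 other settings. The serotonergic neuron list had 3 of 14 higher with a median of 0.16 inside the random range (percentile 95.9). The genes next to Drd2 on its chromosome had 3 of 12 lower (median -0.32, percentile 1.34, kept in 6 of 8 other settings). In all, 409 genes were at least 2-fold higher and 286 lower among 15640 compared (r = 0.958); median scaling gave 619 higher and 74 lower.

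The knockouts were closest to each other, with 23 genes at least 2-fold higher in D2LR-KO than in D2R-KO and 8 lower among 15606 compared (r = 0.994). Higher in D2LR-KO were Ttr (4.45-fold, 20.3 against 193.1), the growth factor Igf2 (3.58-fold), Itpka (2.89-fold), Tagln (2.83-fold), Acta2 (2.75-fold) and Crabp2 (2.73-fold). Prl was 5.66-fold, Glul 3.94-fold, Pomc 3.56-fold, Slc6a5 2.87-fold and Gh 2.26-fold lower, and Mbl2 had a log2 fold of -1.58. The meninges and fibroblast list had 9 of 11 higher (median 0.83, percentile 100), with Dcn at 1.09 and Igfbp2 at 1.02, the blood list 3 of 6 (median 0.55, percentile 100) and the endothelial and pericyte list 3 of 16 (median 0.20, percentile 100). Microglia markers had 1 of 15 higher, Tyrobp at 0.77 (median 0.24, percentile 99.99), interferon response a median of 0.15 (percentile 100), inflammatory cytokines and acute phase a median of 0.06 (percentile 99.9), and choroid plexus and ependyma a median of 0.08 (percentile 99.3). Pan-neuronal genes had a median of -0.26 (percentile 0.02), with Eno2 at -0.97, and serotonergic neuron genes a median of -0.10 (percentile 0.52), with Slc6a4 at -0.63 and Tph2 at -0.58. Housekeeping genes had 1 of 12 lower past 1.5-fold (median -0.17, percentile 0.80) and glucocorticoid-induced genes 1 of 18 (median -0.11, percentile 0.65), places kept in 6 and 7 of 9 other settings. The GABA list at -0.13 (percentile 1.55) and the neuropeptide list at 0.05 (percentile 98.2) turned to 0.05 and -0.04 with the background around each spot, and kept their places in 4 and 5 of 9 other settings. Median scaling gave 11 genes higher and 13 lower, and the values as deposited gave 292 higher and 215 lower.

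The comparisons against non-stressed WT share that single array, so list medians that agree on all 3 stressed arrays can come from it. Against stressed WT, immediate early genes stood at percentiles 31.2 in D2R-KO and 33.4 in D2LR-KO, and GABA genes at 23.0 and 10.2. The choroid plexus and ependyma list stood at 1.51 and 8.55 there. The knockouts had 31 lower genes in common, out of 50 in D2R-KO and 48 in D2LR-KO, and 5 higher genes out of 18 and 17. Independent lists of those sizes would share 0.156 lower and 0.0198 higher genes, but the common control array raises overlaps without any group effect. Simulated arrays with no group effect, drawn without the stressed WT array, had smaller lower lists (19.4 and 19.5 genes) that shared 9.87 genes on average (3 to 18). Their higher lists of 19.9 and 20.4 genes shared 3.95 (0 to 10). The spread of all simulated arrays was drawn from the differences between the real arrays and holds any real group effect. Simulated overlaps and covariances are therefore no pure measure of chance. As a share of the smaller list the observed overlap was 64.6% against 55.5% simulated for lower genes and 29.4% against 21.7% for higher genes; simulated with all 4 arrays, the shares were 24.2% and 30.3%, so the higher overlap did not exceed that simulation. Fold changes of the knockouts correlated at r = 0.687 across genes (simulated 0.500), with a covariance of 0.0330 against 0.0210 in the simulation, a difference of 0.0120 (-0.0276 when all 4 arrays were simulated); genes are not independent replicates. Stressed WT shared 12 lower and 2 higher genes with D2R-KO, and 17 lower and 0 higher genes with D2LR-KO, where simulated arrays with no group effect, whose lists differ in size from these, shared 34.4 and 44.4, and 34.5 and 44.7. As a share of the smaller list the lower overlaps were 24% with D2R-KO (23.7% simulated) and 35.4% with D2LR-KO (23.9% simulated), and the higher ones 11.1% (29.9% simulated) and 0% (30.4% simulated). The fold changes of stressed WT correlated at r = 0.061 across genes with those of D2R-KO and at 0.135 with those of D2LR-KO, against 0.500 and 0.499 in simulated arrays with no group effect. Simulated values near 0.500 follow from the shared control and the equal spread alone. The folds of stressed WT had an SD of 0.422, against 0.223 in D2R-KO and 0.213 in D2LR-KO. Equal spread therefore did not hold, and no shortfall of these correlations or overlaps from chance can be read from the simulation. No gene was at least 2-fold higher and 11 were at least 2-fold lower on all 3 stressed arrays. By the smallest of their 3 differences these were led by Ch25h (-1.95, -1.95 and -1.96 in stressed WT, D2R-KO and D2LR-KO), Ddit4 (-1.76, -2.04 and -2.25), Ecrg4, a peptide precursor of choroid plexus (-1.34, -1.55 and -1.27), the folate receptor Folr1 (-1.13, -1.54 and -1.46), Icam5 (-1.46, -1.74 and -1.12), Gprasp1 (-1.29, -1.07 and -1.13), Rbbp4 (-1.07, -1.11 and -1.04) and Ak5 (-1.03, -1.17 and -1.04). Simulated arrays of equal spread, with stressed WT included, shared 20.4 lower and 29.4 higher genes among all 3, since the wider spread of the stressed WT array then enters every simulated array. The control array cannot be divided, so part of any excess over these values can come from it.

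Pairs of comparisons with no array in common were correlated over 14704 genes detected on all 4 arrays. Stressed WT against non-stressed WT and D2LR-KO against D2R-KO gave Pearson's r = 0.089 and Spearman's rho = 0.118. D2R-KO against non-stressed WT and D2LR-KO against stressed WT gave 0.272 and 0.228, and D2LR-KO against non-stressed WT and D2R-KO against stressed WT gave 0.208 and 0.130. These are correlations across genes, which are not independent replicates. With the background around each spot all 3 Pearson values were slightly below 0 (-0.056, -0.045 and -0.0007), while median scaling gave 0.383 for the 1st pair and -0.076 for the last.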

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

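The tests on serotonergic share, hindbrain tissue and choroid plexus tissue were chosen only after the results they concern had been seen.

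Some differences from non-stressed WT had opposite signs in different stressed groups, and none of them was tested. With the background around each spot stressed WT turned to 0.084 for Tph2 and 0.046 for the endothelial and pericyte list, so these 2 lose their opposite signs there. Tph2 was lower in stressed WT and higher in D2R-KO, log2 folds 2.76 apart, and higher in D2LR-KO, 2.19 apart. The meninges and fibroblast list was 0.93 higher in D2LR-KO than in stressed WT and 0.78 higher than in D2R-KO. The endothelial and pericyte list was 0.55 higher in D2LR-KO than in stressed WT, and the blood list was 0.50 higher in D2LR-KO than in D2R-KO. The meninges, endothelial and blood lists mark tissues and cells, and whether the share of these differed in the D2LR-KO pool was not tested. Probes without a gene name here are outside the comparisons. In stressed WT 119 of 6147 of them were at least 2-fold higher than in non-stressed WT and 156 lower, against 4 of 6151 higher and 18 lower in D2R-KO, and 3 of 6108 higher and 12 lower in D2LR-KO.

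The stressed WT array stood furthest from the others, with 8.29 times as many genes past 2-fold against non-stressed WT as D2R-KO. Before scaling between arrays its positive control spots were also the dimmest. Their mean log2 signals were 13.1 and 11.9, against 13.5 to 13.7 and 12.0 to 12.4 on the other arrays. Array-wide scaling or a smooth brightness-dependent trend was examined under cyclic loess, where the ratio of 8.29 was still 5.02, above the limit written beforehand. The main values were already quantile-normalized, which also removes such trends, so cyclic loess was no separate check and cannot decide on this cause. The values show only that a large ratio remained after either normalization. Other faults of the stressed WT array were not excluded. The background around each spot lowered the ratio to 1.68, so how far background handling contributes stays open. Forced swim stress as the only cause is unlikely, because the 229 genes higher in stressed WT were little changed in the knockouts. Their medians were 0.0051 in D2R-KO and 0.059 in D2LR-KO (SD 0.230 and 0.183). The limit of 0 written beforehand was not met, however, and the SDs were brought in afterwards. Of the 335 genes lower in stressed WT (medians 0.024 and -0.073 in the knockouts), 12 were also at least 2-fold lower in D2R-KO and 17 in D2LR-KO. The shared control array raises such overlaps by itself. As a share of the smaller list they were 24% with D2R-KO (23.7% simulated) and 35.4% with D2LR-KO (23.9% simulated). A contribution of stress for single genes stays open. Non-specific or degraded signal cannot be told apart from other causes, because chemosensory receptor genes had a lowest median log2 fold of 0.046 over the other 3 arrays but lay far below the offset (median signal 7.35 to 7.47 over the blank level), while 418 of 544 were higher than in non-stressed WT, with median deposited intensities of 4.9 against 3.2. An effect of stress that needs the D2 receptor was not tested and may still contribute, since a non-stressed knockout array and replicate arrays are lacking.

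Serotonergic neuron genes were higher on both knockout arrays than on both WT arrays for 7 of 14 markers, namely Tph2, Slc6a4, Slc18a2, Gch1, Gchfr, Gata2 and Slc22a3. Slc22a3 was dim on every array (deposited intensities 1.9 to 5.6). Of the markers that did not follow, Lmx1b (4.2 to 10.8), Htr5b (6.2 to 10.1), En1 (10.6 to 14.1) and En2 (9.7 to 13.2) were also dim. The offset shrinks the folds of such dim markers. The brighter Ddc, Gata3 and Maob did not follow either. Ddc fell short only by a log2 fold of -0.046 in D2R-KO against non-stressed WT, within the control spot SD of 0.167. As deposited it was higher on both knockout arrays (1735.3 in D2R-KO, 2253.8 in D2LR-KO) than in non-stressed WT (1562.6) and stressed WT (1119). Whether Ddc follows thus depends on the processing, while Gata3 and Maob did not follow as deposited either. A larger share of serotonergic cells cannot be told apart from regulation of single genes, as 50% of markers followed and that share rests partly on dim markers. More hindbrain tissue in the knockout dissections would fit, because the pons and medulla list stood at percentile 100 in all 4 comparisons of a knockout with a WT array. Of that list's 14 genes 10 were on the array, all 10 were detected on every array, and 1 also stands in another list; deposited intensities of Hoxb5 were 50.6, 4.2, 141.1 and 108.0 in non-stressed WT, stressed WT, D2R-KO and D2LR-KO. An effect of genotype on these genes stays open and was not tested.

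Ttr was far higher on both WT arrays than on both knockout arrays. The difference was not confined to Ttr, because 5 of 7 other choroid plexus genes were higher on both WT arrays. These were Folr1, Kcne2, Clic6, Otx2 and Aqp1, while Kl and Cldn2 did not follow. Regulation of Ttr alone would therefore not account for the pattern. Choroid plexus tissue in the pooled dissections stays open as a source, since the number that followed lay between the limits set for this test. The deposited intensities of Folr1 were 62.8, 13.4, 2.2 and 3.9 in the same order of arrays, those of Kcne2 45.6, 9.9, 7.6 and 4.0, and those of Clic6 39.2, 9.2, 5.2 and 4.9. No biological explanation was tested for this pattern.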

How the results depend on the processing

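No tests were run for this part, and 2 of its settings, the background around each spot and quantile normalization without the stressed WT array, were chosen only after the data had been seen. No paired analysis was possible because every group has 1 array and all replicate numbers are 1. Counts of genes past the threshold stayed within 1.5 times under cyclic loess, the mean of all probes, the filters on dim genes and quantile normalization without the stressed WT array. Over all settings, 72 counts stayed within that range and 78 moved, and 504 gene values stayed within the spread of repeated control spots, 362 moved and 7 reversed. Of the list medians 1143 stayed, 198 moved and 9 in the lowest or highest 2.5% of random lists changed sign, and of the correlations 19 stayed, 2 moved and 3 reversed. Of 60 list medians in the lowest or highest 2.5%, 32 stayed there in every setting, 14 left it in 1 setting and 14 in more. The cause was not tested. Signal over background limits dim genes, since the offset of 50 lies above the signal of many of them, and a smaller offset or plain subtraction raises their folds by construction.

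Counts are given as higher and lower. At 1.5-fold they were 1139 and 1268 for stressed WT against non-stressed WT, 90 and 231 for D2R-KO and 116 and 219 for D2LR-KO against it, 1458 and 1353 for D2R-KO and 1364 and 1283 for D2LR-KO against stressed WT, and 104 and 52 for D2LR-KO against D2R-KO. At 3-fold, in the same order of comparisons, they were 14 and 39, 4 and 12, 2 and 9, 60 and 26, 60 and 14, and 2 and 3. With an offset of 16 they were 488 and 694, 28 and 104, 35 and 85, 810 and 696, 781 and 571, and 45 and 13. Plain subtraction with a floor gave 1408 and 1677, 220 and 397, 203 and 357, 1790 and 1606, 1742 and 1496, and 227 and 124. The value table as deposited gave 1662 and 1837, 353 and 422, 293 and 406, 2339 and 1627, 1944 and 1649, and 292 and 215. The background around each spot gave 749 and 576 for stressed WT, 532 and 256 for D2R-KO and 496 and 134 for D2LR-KO against non-stressed WT, and 105 and 63 for D2LR-KO against D2R-KO. Scaling to a single median gave 30 and 893 for stressed WT and 8 and 74 for D2LR-KO against non-stressed WT, 1129 and 49 for D2R-KO and 619 and 74 for D2LR-KO against stressed WT, and 11 and 13 between the knockouts.

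With the background around each spot the direction reversed for Dnajc7 (0.75), Paip2 (1.72), Slc17a6 (0.95) and Tph2 (0.084) in stressed WT, for Gria1 (3.90) and Sgk1 (0.75) in D2LR-KO against non-stressed WT, and for Drd2 (-0.090) between the knockouts. The endothelial and pericyte median in stressed WT (0.046), the astrocyte median in D2R-KO (0.061) and the ribosomal protein median in D2LR-KO against stressed WT (-0.043) reversed too, as did the pan-neuronal (0.012) and glutamate (0.033) medians in D2LR-KO against non-stressed WT and the GABA (0.048) and stress neuropeptide (-0.041) medians between the knockouts. Under that setting the correlations of comparisons with no array in common were -0.056 for the pair with stressed WT against non-stressed WT, -0.045 for the pair with D2R-KO against non-stressed WT and -0.000716 for the pair with D2LR-KO against non-stressed WT. Median scaling gave 0.383 for the 1st of these and -0.076 for the last, and 0.0092 for the median of the genes next to Drd2 in D2R-KO against stressed WT and -0.051 for oxidative phosphorylation in D2LR-KO against non-stressed WT.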

Other observations

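The pons and medulla percentiles of knockout against WT arrays belong to tests chosen only after the result was seen, and the 8 region lists were written after a few gene values had been seen.

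Genes that mark the hindbrain differed between WT and knockout arrays. The pons and medulla list had a median log2 fold of 0.40 in D2R-KO and 0.38 in D2LR-KO against non-stressed WT, with 3 of 10 members higher in each and 0 and 1 lower, and of 0.59 in both against stressed WT, with 5 of 10 higher (percentile 100 in all 4). In stressed WT against non-stressed WT it was -0.21 (percentile 2.38). Hoxa5, a homeobox gene of the hindbrain and spinal cord, had deposited intensities of 31.3, 1.8, 77.2 and 95.6 in non-stressed WT, stressed WT, D2R-KO and D2LR-KO, and Hoxa2 had 7.7, 2.5, 21.0 and 21.8. Genes of cerebral cortex and hippocampus were lower in both knockouts, with list medians of -0.18 (percentile 0.02) and -0.16 (percentile 0.05) against non-stressed WT and with 4 of 12 lower and 1 higher (Lamp5 at 0.85) in D2R-KO and 2 of 12 lower in D2LR-KO, while in stressed WT the median was 0.07 (percentile 69.2). Against stressed WT the list median was -0.21 in each knockout, inside the random range (percentiles 5.17 in D2R-KO and 4.94 in D2LR-KO). Nrgn, a postsynaptic calmodulin-binding protein of forebrain neurons, had intensities of 618.3, 1094.5, 316.1 and 310.4 in the same order, and the cortical transcription factor gene Neurod6 had 138.1, 113.8, 56.2 and 47.1.

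The other region lists are given for D2R-KO, D2LR-KO and stressed WT against non-stressed WT. Medians were 0.14, 0.08 and 0.25 for thalamus (percentiles 99.1, 94.3 and 96.3), and 0.15, 0.00 and -0.01 for midbrain tectum and periaqueductal grey (99.95, 48.3 and 41.9). They were -0.12, -0.01 and 0.12 for ventral midbrain dopamine nuclei (1.30, 39.3 and 83.6), -0.05, -0.01 and 0.06 for hypothalamus (1.37, 37.6 and 92.3), 0.00, -0.03 and -0.04 for striatum (48.4, 15.6 and 22.1), and 0.16, 0.03 and 0.07 for pineal and pituitary (99.9, 86.1 and 92.2). In the pineal and pituitary list 3 of 7 genes were higher in D2R-KO. Of the ventral midbrain list 8 of 10 genes also stand in another list, and of the hypothalamus list 5 of 12.

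RNA from a neighbouring brain region was examined as a source of the differences of the stressed WT array. No region list was in the highest 2.5% of random lists against all 3 other arrays, and the closest was hypothalamus, whose lowest percentile was 92.28. The outcome written beforehand for its absence was thus met, but that outcome covered only lists that are higher. On the lower side the pons and medulla list was in the lowest 2.5% on the stressed WT array against all 3 others, with percentiles of 2.38 at most. The regional make-up of the tissue may therefore have differed, and this source cannot be told apart from others; the lower side was examined only after the percentiles had been seen.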
